A study of Arabidopsis thaliana with 6 samples.

How the data were processed

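Transcript levels were measured on 6 Affymetrix arrays, each hybridised with biotin-labelled cRNA made from 7 µg of total RNA of whole Arabidopsis thaliana seedlings, per the labels' protocols. The deposited values are intensities on a linear scale, 1 per probe set and array, and a probe set is the group of short probes on the array that reads a transcript. Per the labels, the authors followed the manufacturer's standard protocol, while the summary algorithm, the background correction and the scaling are not given in the sources used here. The deposited intensities had medians between 155.7 and 169.2 on the 6 arrays, so the authors' values were already at about 1 level, and between 163 and 213 values per array lay below 0, as happens after background subtraction. Because the scaling is not known, an intensity can be compared between arrays for a given probe set, but a difference in intensity between probe sets is not read as a difference in transcript amount. Where the naming rule, the floor or a filter used the level of probe sets, it did so only as a measure of signal over background.

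The arrays were grouped by their titles into 3 water and 3 chitooctaose arrays. The labels disagree in a pair of places. The series text gives an exposure of 3 min where titles and protocols give 30 min, and the short description of the chitooctaose arrays names water where their titles, growth protocols and treatment protocols name chitooctaose. Titles and protocols were followed. The replicate numbers of the titles were not used in the model.

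The table held 22810 probe sets, of which 64 Affymetrix controls were left out, and 22746 were tested. Names came from the platform annotation, updated through a RefSeq gene table of the assembly TAIR10.1. Of the tested probe sets, 13513 had exactly 1 gene, 503 had several and 8730 had none in this annotation. Of those with 1 gene, 13436 matched the gene table and 77 kept the platform's name. They covered 13350 genes, 88.4% of them under a locus code alone. Probe sets with several genes were never named. As no genome build was stated for the array, no coordinates were used.

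Intensities below a floor of 16 were set to 16 (3.81 to 4.91% of the values of an array) and log2 was taken. A linear model was fitted to each probe set with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3, comparing chitooctaose with water in a 2-sided test. The p-values were adjusted by Benjamini-Hochberg over all tested probe sets, and an adjusted p under 0.05 is called changed. Fold changes are differences of mean log2 values turned into ratios, and where all 3 arrays of a group were at the floor the ratio is a lower bound and is given as at least that many fold. Means ± SD are of the deposited intensities, with n = 3 arrays per group, and SE is that of the model. All adjusted p-values of single genes come from this limma model.

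Before the data were examined, 23 gene lists, the rule for naming genes and the alternative settings were fixed. The rule named 7 genes to be reported always (CERK1, LYK5, LYK4, MPK3, WRKY33, WRKY53 and RBOHD), the 8 largest rises and 8 largest falls among changed probe sets with exactly 1 gene and no overlap between the groups, and from each list the 2 changed members with the largest change, or the member with the highest mean where none had changed. Each gene was represented by its probe set with the highest mean. The rule named 36 genes. Of the 7 genes to be reported always, only WRKY53 was on a probe set with a name here, and the other 6 are not analysed here. In the lists, 86 of 844 entries had a named probe set, so 5 lists had no member (immunity marker genes, ERF and DREB factors, MYB factors, heat shock genes and root markers), 12 had 1 to 4, and 6 had at least 5 and were tested as sets. The tested lists had named probe sets for 9 of 18 calcium-binding and touch-induced genes, 7 of 72 WRKY genes and 13 of 39 ubiquitin ligase genes. For chitinases it was 8 of 13, for auxin genes 12 of 122 and for ribosomal protein genes 16 of 84. Members with a named probe set are called measured below, and the others may be on probe sets without a name here. Genes outside the rule that are named below were chosen after their values were seen.

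The 6 lists were tested with limma's camera, which compares a list's genes with all other genes, at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 6 lists. Camera was repeated with the correlation estimated from the data, and fry, which asks whether a list's genes move on balance in 1 direction, was run beside it. The list written as ribosomal protein genes had been meant for the cytosol, but apart from AT1G77750 its matched members were rpl and rps genes of the plastid genome, and it is described as such.

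The scripts were tested on simulated arrays with 200 of 22746 probe sets changed by a known amount. The changed ones were drawn from probe sets with a mean above 6 on the log2 scale in water, so the shares called do not cover dimmer ones. Noise was drawn independently for each value at the model's variances. At a true change of 1 on the log2 scale 88% were called in the simulated comparison of chitooctaose with water, at -1 80%, and at 2 and -2 100%. Of 194 calls 10 were false (5.15%). The arrays' number limits the precision of every value, and p-values measure the spread between these 6 arrays, which the series describes as biological replicates.

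Alternatives covered quantile normalization, median centring, the variance model, the floor (1 and 64), leaving out the dimmest 40% of probe sets, the replicate number as a block, leaving out each array, a test without variance shrinkage, stricter thresholds, and 1 probe set per gene. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 handled names and plots.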

Results

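Whole Arabidopsis thaliana seedlings of the Col-0 ecotype, 14 days old and grown in shaken liquid medium, were exposed for 30 min to chitooctaose at 1 µM or to the same volume of water (20 µl in 10 ml of medium). Chitooctaose is a fragment of chitin, the N-acetylglucosamine polymer of fungal cell walls, and plants sense such fragments through receptor kinases with LysM domains. There were 3 arrays per treatment. Across the 22746 tested probe sets, log2 intensities correlated with Pearson's r between 0.977 and 0.984 for the 6 pairs of arrays within a treatment and between 0.954 and 0.962 for the 9 pairs across treatments. These correlations are across genes, which are not independent replicates. The ratio of 3' to 5' probe sets, a sign of RNA integrity, was 1.28 ± 0.0548 (SD, n = 3) for actin in water and 1.31 ± 0.0845 (SD, n = 3) in chitooctaose, and 0.809 ± 0.0319 against 0.807 ± 0.0181 for ubiquitin.

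The comparison of chitooctaose with water asked which transcripts respond to the chitin fragment within 30 min. WRKY53, a transcription factor gene of defence and leaf senescence, rose 30.2-fold, from an intensity of 57.3 ± 2.08 in water to 1732 ± 84.6 in chitooctaose (SD, n = 3). STZ, which encodes a zinc finger repressor of stress responses, rose 22.8-fold, from 204 ± 52.3 to 4567 ± 167. BIK1, a cytoplasmic kinase that acts below immune receptors, rose 2.21-fold, from 669 ± 67.3 to 1472 ± 42.6. AT5G61590, which the gene table also lists as DEWAX, a repressor of wax synthesis, fell 3.50-fold, from 1013 ± 131 to 288 ± 15.8. In all, 964 probe sets rose and 183 fell, together 5.04% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05).

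**Figure D1:**
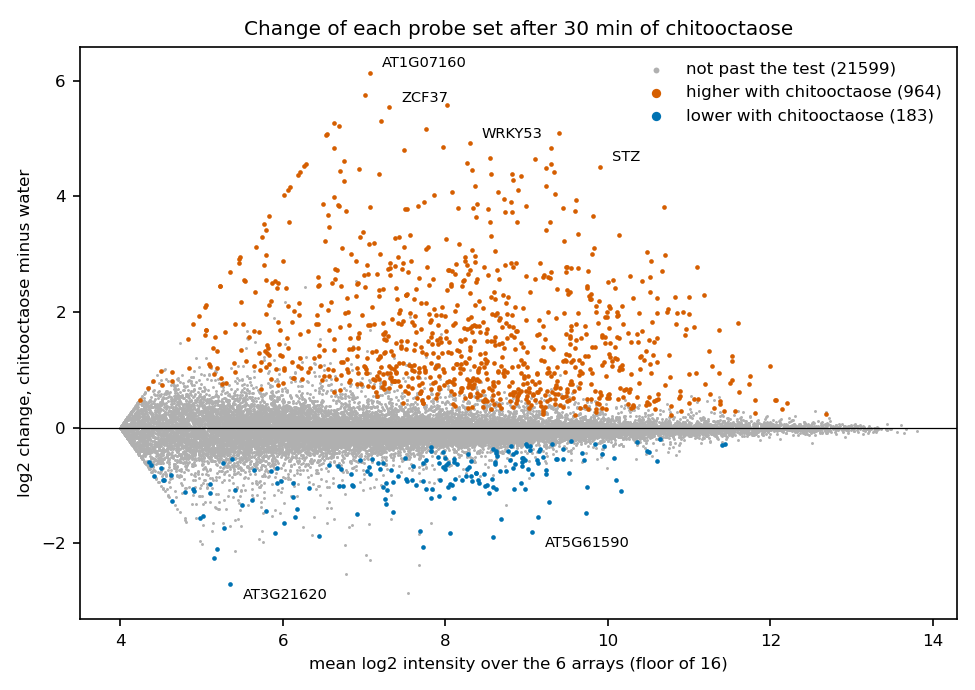
Change of each tested probe set on the log2 scale (chitooctaose minus water, 3 arrays each) against its mean log2 intensity over the 6 arrays. Orange points are the 964 probe sets that rose and blue points the 183 that fell, and AT1G07160, at the floor in water, had a fitted change of 6.13 where AT3G21620, at the floor in chitooctaose, had one of -2.71.

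Rises were larger than falls. The median change was 1.35 on the log2 scale among the probe sets that rose and -0.78 among those that fell, while the median over all tested probe sets was -0.04. A rise of at least 2-fold was called for 633 probe sets, and one of at least 8-fold for 108, while 54 fell at least 2-fold. The groups did not overlap for any of the 1147 called probe sets, and they did not overlap for 19.2% of all tested ones, where chance gives 10%. The number of falls was 86 without water replicate 1, 176 without water replicate 2 and 95 without water replicate 3. It was 95 without chitooctaose replicate 1, 105 without chitooctaose replicate 2 and 103 without chitooctaose replicate 3. The number of rises was lower too, at 721 to 835. With an array left out fewer arrays enter the test, which can lower the counts. All of these runs had the same number of arrays, so that does not account for the differences between them. The number of falls thus depended on which array was left out and was lowered least without water replicate 2, and the cause was not tested.

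Among genes on a named probe set, the 8 largest fitted rises included AT1G07160, a protein phosphatase gene, which rose at least 70.2-fold. AT1G07160 was at the floor in all 3 water arrays and at 1125 ± 50.7 in chitooctaose (SD, n = 3, adjusted p = 9.05e-06). AT1G24140, a matrix metalloproteinase gene, was at the floor in all 3 water arrays too and rose at least 38.5-fold, to 617 ± 52.5 (adjusted p = 1.48e-05). AT3G01830, AT1G35210 and ZCF37 rose from water levels near the floor, with 1 water array at it for each, so their sizes are not exact. Their fitted log2 changes were 5.76, 5.22 and 5.54, against 7.09, 5.95 and 5.77 with a floor of 1 and 3.89, 3.31 and 4.08 with a floor of 64. AT2G22880 rose 47.9-fold, from 39.9 ± 18.4 to 1793 ± 72.1, and AT5G52760 39.5-fold, to 938 ± 189. WRKY53 had a log2 change of 4.92 (SE 0.07, adjusted p = 9.05e-06), and each of the 8 genes was higher in every chitooctaose array than in any water array. The fitted log2 changes of AT1G07160 and AT1G24140 were 10.13 and 7.07 with a floor of 1 and 4.13 and 3.27 with a floor of 64, and with the latter those of AT2G22880 and AT5G52760 were 4.81 and 3.86, all past the threshold.

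Among the 8 largest falls of genes on a named probe set, beside AT5G61590, AT3G21620 fell from 106 ± 25.1 in water to values at the floor in all 3 chitooctaose arrays, at least 6.53-fold lower (adjusted p = 0.000533). AT5G03230 fell 4.16-fold, from 436 ± 59.0 to 104 ± 3.36 (adjusted p = 0.000274), and AT1G49200 fell 3.47-fold, from 389 ± 59.3 to 112 ± 16.5. AT3G23880 fell 3.54-fold, from 114 ± 21.6 to 32.3 ± 6.39. AT2G03770, listed in the gene table as a sulfotransferase, fell 4.30-fold from 83.4 ± 41.8 in water, to near the floor, and AT5G58340 fell 3.34-fold, to 18.4 ± 10.3, each with 1 chitooctaose array at the floor, so these sizes are not exact. CYP718, a cytochrome P450 gene, fell 3.15-fold, from 115 ± 4.63 to 38.2 ± 13.3, with a log2 change of -0.84 in place of -1.66 with a floor of 64. The call of AT2G03770 (adjusted p = 0.0417) was lost without water replicate 1 (adjusted p = 0.158) or 3 (0.0629) and without chitooctaose replicate 1 (0.156), 2 (0.154) or 3 (0.133), that of AT5G58340 (0.0186) without water replicate 1 (0.0788) or 3 (0.0861) and chitooctaose replicate 1 (0.0766) or 3 (0.0558), and that of CYP718 (0.0352) without water replicate 1 (0.138), 2 (0.118) or 3 (0.122) and chitooctaose replicate 1 (0.0603) or 3 (0.0852). With a floor of 64, above many of these values, the calls of AT3G21620 (0.156), AT3G23880 (0.0731), AT2G03770 (0.706) and AT5G58340 (0.564) ended, and that of AT5G58340 also ended with a floor of 1 (0.0965).

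**Figure D2:**
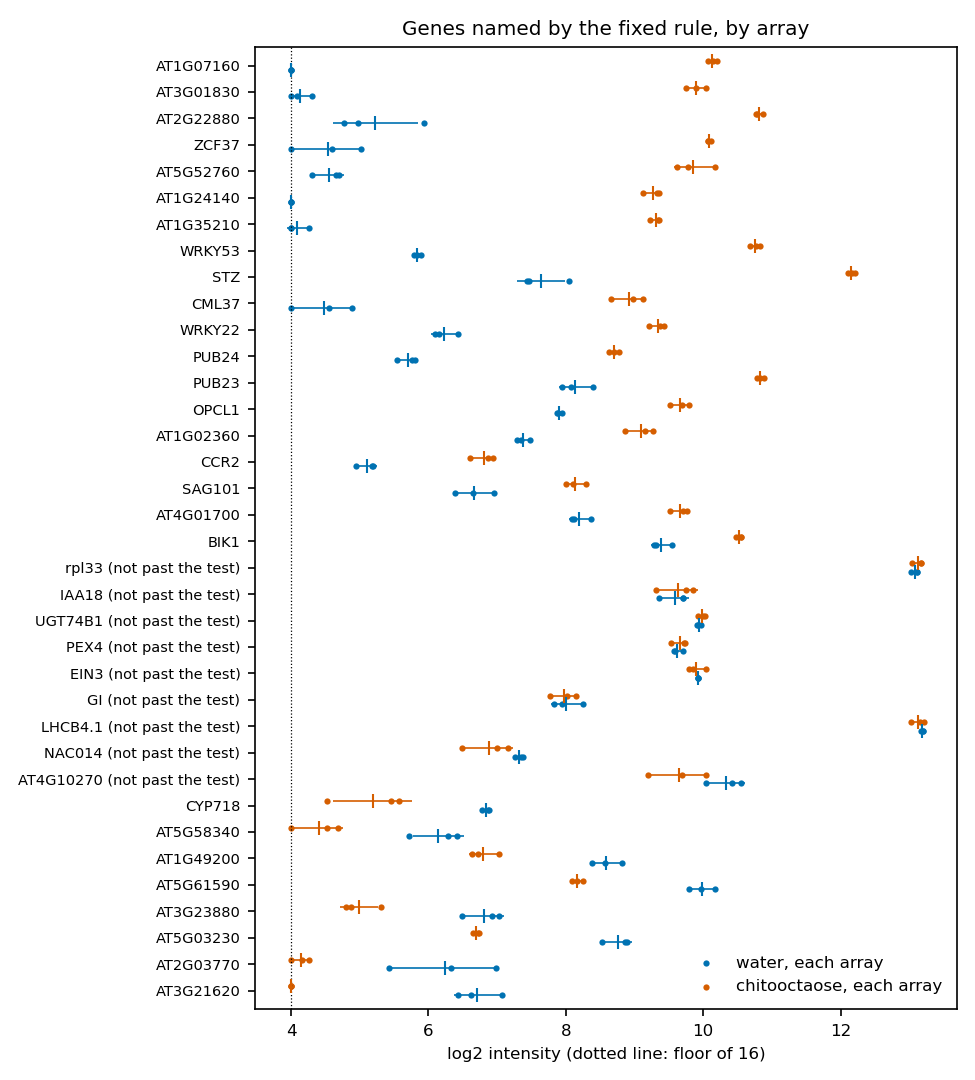
Log2 intensity on each of the 6 arrays (points) for the 36 genes taken by the naming rule, with the mean and SD of each group of 3 arrays as a tick and bar, ordered by the change. WRKY53 stood at 57.3 in water and 1732 in chitooctaose on the linear scale, and genes marked as not past the test had an adjusted p of 0.05 or more.

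Of the 9 measured calcium-binding and touch-induced genes, which encode calmodulin-like calcium sensors, 6 rose, none fell and 3 did not pass the test. Besides AT3G01830, CML37 rose 21.8-fold, from 20.9 ± 10.1 to 491 ± 78.9 (SD, n = 3, adjusted p = 0.000290), with 1 water array at the floor and a log2 change of 2.93 with a floor of 64 in place of 4.45. Also higher were CML38 (4.95-fold), CML23 (4.34-fold), CML42 (2.64-fold) and CML41 (1.80-fold). AT1G76640, AT3G47480 and CML43 had log2 changes of 0.42, 0.26 and 0.19 and did not pass. The list stood apart from other genes (camera, adjusted p = 3.79e-12, or 0.0102 with an estimated correlation), with a median log2 change of 1.40, and adjusted over the list alone 7 members rose. The call of CML41 (adjusted p = 0.0257) was lost without water replicate 1 (0.107), 2 (0.0755) or 3 (0.107), without chitooctaose replicate 1 (0.0754) or 3 (0.0928), and with a floor of 64 (0.362).

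WRKY transcription factors, which bind W-box promoter elements of defence genes, had 7 measured members of 72 listed. Of these 7 genes 3 rose, none fell and 4 did not pass. After WRKY53 came WRKY22, a factor below immune MAP kinases, which rose 8.68-fold from 75.1 ± 9.57 to 649 ± 48.3 (SD, n = 3, adjusted p = 6.14e-05), and WRKY6, which rose 4.03-fold from 139 ± 10.2 to 559 ± 44.7. WRKY42, WRKY47, WRKY20 and ZAP1 had log2 changes between -0.14 and 0.18. The list passed camera (adjusted p = 1.72e-05, or 0.0276 with an estimated correlation), and adjusted over the list alone 3 rose. Its mean log2 change was 1.45 against a median of 0.18.

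Of 13 plant U-box and ATL ubiquitin ligase genes, 4 rose, none fell and 9 did not pass. All 4 were U-box genes. PUB24 rose 7.99-fold from 52.3 ± 5.04 to 417 ± 21.9, PUB23 6.45-fold from 284 ± 47.2 to a mean of 1819, PUB22 5.91-fold from 167 ± 11.9 to 986 ± 36.2 and PUB25 2.11-fold from 116 ± 15.0 to 243 ± 9.69 (SD, n = 3). PUB22, PUB23 and PUB24 are known as negative regulators of immune signalling. The list passed camera (adjusted p = 1.72e-05, or 0.0276 with an estimated correlation). Adjusted over the list alone, 4 rose and 1 fell, the latter being ATL63 with a log2 change of -0.65 (adjusted p = 0.187 over all probe sets).

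Genes of chitinases, enzymes that hydrolyse chitin, and of chitinase-like proteins had 8 measured members, of which 2 rose, none fell and 6 did not pass. AT1G02360 rose 3.30-fold, from 166 ± 11.3 to 550 ± 78.9, and AT4G01700 2.76-fold, from 294 ± 31.6 to 811 ± 69.7 (SD, n = 3). The list passed camera (adjusted p = 7.55e-05, or 0.0338 with an estimated correlation). Adjusted over the list alone 3 rose, the third being AT2G43620 with a log2 change of 1.10, which missed the threshold over all probe sets (adjusted p = 0.0575) and passed it after median centring (0.0148), with robust variances (0.0109), without the dimmest 40% of probe sets (0.00588) and with a floor of 1 (0.0338). AT2G43590 stood at 3762 ± 200 in water and 4011 ± 195 in chitooctaose and did not pass.

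**Figure D3:**
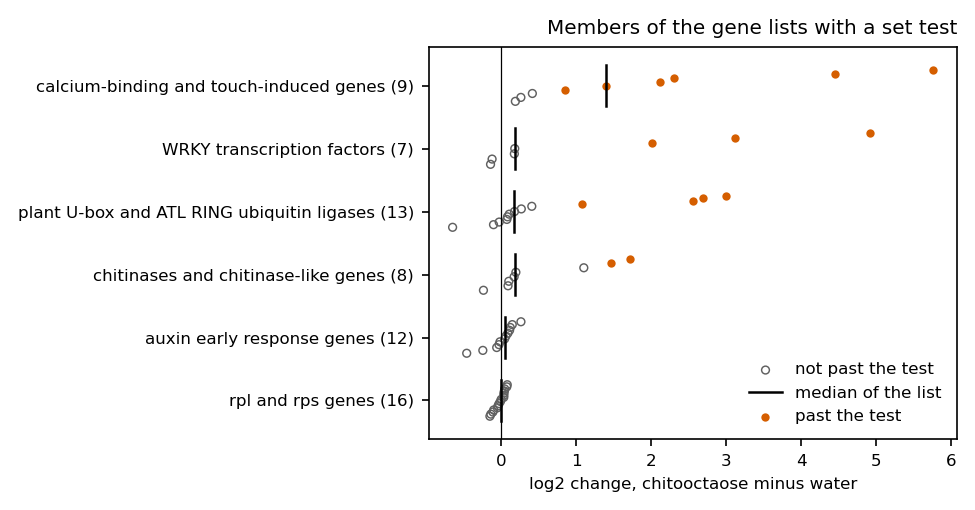
Log2 change (chitooctaose minus water) of each member of the 6 gene lists with a set test, with the number of measured members in brackets, filled points for members past the test over all probe sets and a line at the median of the list. The calcium-binding and touch-induced genes had a median of 1.40, and no member of the auxin list or of the rpl and rps genes passed.

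Lists with fewer than 5 measured members had no set test. OPCL1, an enzyme gene of jasmonate synthesis, rose 3.39-fold, from 239 ± 6.12 to 813 ± 78.2 (SD, n = 3), and was the measured member of the jasmonate list. SAG101, a partner of the immune regulator EDS1 and the measured member of the salicylic acid list, rose 2.77-fold, from 103 ± 20.6 to 282 ± 29.8. CCR2, a reductase gene of lignin synthesis, rose 3.24-fold, from 34.7 ± 3.20 to 113 ± 13.4, or by a log2 change of 0.81 in place of 1.70 with a floor of 64, while HCT of the same pathway had a log2 change of -0.17 and did not pass. BIK1 rose and AT5G18610 did not pass in the chitin perception list, and STZ rose and AT3G53600 did not pass in the zinc finger list. Adjusted over the list alone, each of these 5 lists had 1 rise. In the ethylene list neither member passed over all probe sets. PDF1.2, a defensin gene, stood at 97.6 ± 9.57 in water and 464 ± 405 in chitooctaose, with a log2 change of 1.91 (adjusted p = 0.189). It passed adjusted over the list alone, without chitooctaose replicate 3 (log2 change 1.24, adjusted p = 0.0139) and without the dimmest 40% of probe sets (adjusted p = 0.0343). EIN3, the ethylene signalling factor, stood at 972 ± 3.79 and 955 ± 85.0 (adjusted p = 0.915).

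Other groups held no measured gene past the test, but few of their genes had a named probe set. It was 12 of 122 auxin genes, 1 of 100 NAC genes and 3 of 25 light-harvesting and Rubisco genes. Of 19 tryptophan, glucosinolate and camalexin genes it was 1, and of 15 clock genes 1. The results below therefore do not speak for the whole families. None of 12 auxin early response genes passed, over all probe sets or adjusted over the list alone, and the list did not stand apart (camera, adjusted p = 0.738, median log2 change 0.06). IAA18, taken by the naming rule, stood at 776 ± 103 in water and 807 ± 153 in chitooctaose (SD, n = 3). None of 16 rpl and rps genes passed, nearly all of them plastid ribosomal protein genes (camera, adjusted p = 0.738, log2 changes from -0.15 to 0.08), and rpl33, taken by the naming rule, had a change of 0.05. Their mean log2 change was -0.02 while camera's direction was up, as it compares the list with the other genes. The light-harvesting genes LHCB4.1, LHCB4.2 and LHCB4.3, shoot markers, had log2 changes of -0.05, -0.08 and 0.20, and the clock gene GI one of -0.03. PEX4, AT2G28390 and AT4G34270, used as reference genes, had changes of 0.04, -0.02 and -0.05. UGT74B1 of glucosinolate synthesis stood at means of 981 and 1010, NAC014 at 161 ± 6.86 and 120 ± 27.2, and the low oxygen gene AT4G10270 at 1309 ± 234 and 823 ± 237, with adjusted p of 0.776, 0.388 and 0.283. AT4G17260, the other low oxygen gene, had a change of 0.03. Adjusted over the list alone, no member of these lists passed.

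Probe sets without a gene name here changed more often than those with exactly 1 gene, 6.20% against 4.31% (Fisher's exact test, 2-sided p = 4.87e-10, over probe sets, which are not independent replicates). Of the former 439 rose and 102 fell, and of the latter 505 rose and 77 fell. The largest rises of unnamed probe sets had log2 changes of 5.17, from 39.1 ± 19.2 to 1304 ± 156, and of 5.09, from 119 ± 34.6 to 3940 ± 60.4 (SD, n = 3). Their largest falls had fitted log2 changes of -2.25, with 2 chitooctaose arrays at the floor, so that the size is not exact, and of -1.88. The files do not pair these probe sets with genes.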

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

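The versions without probe sets of shared sequence and without probe sets that touched the floor were chosen after seeing the data, and the others before. The number of rises stayed between 857 and 1060 and that of falls between 158 and 265 under quantile normalization, median centring, other variance models, other floors and without the dimmest 40% of probe sets. The first gave 951 and 265 and shared 1071 of the 1147 calls. Without probe sets of shared sequence 929 rose and 171 fell, and without those touching the floor 1032 and 241. With single arrays left out, 721 to 835 rose and 86 to 176 fell, with fewer arrays in the model. Without variance shrinkage 744 rose and 113 fell, and the cause was not tested. Stricter definitions gave fewer by construction: 62 falls at an adjusted p under 0.01, 633 rises and 54 falls of at least 2-fold, and 479 and 63 with 1 probe set per gene, where fewer were tested. All 4 lists that passed camera did so under every setting run for lists.

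Of the 27 called genes taken by the naming rule, 22 kept their call under each of the 14 settings run for genes (13 for those among the dimmest 40%), and the other 5 are the falls named above. Of the 40 other called genes followed, 20 did. No called gene changed sign.

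With the replicate number as a block, 754 probe sets rose and 93 fell, and 808 of the 1147 calls were kept. With it AT2G03770 (limma, adjusted p = 0.0621), AT5G58340 (0.0976) and CYP718 (0.101) lost their call and AT4G10270 gained one (0.0395). Of the 40 other called genes 17 lost theirs, CML42 (0.0577) and CML41 (0.111) among them. The deviations of same-numbered arrays from their group means correlated at 0.05, 0.03 and -0.10, and 1 of 6 arrays correlated best with its own number. The numbers are therefore not taken to pair the arrays in the model. A correlation of deviations does not register a level shift common to a whole array. The median intensity was lowest for replicate 2 in both treatments, at 155.7 in water and 157.6 in chitooctaose. Some control probe sets also followed the number, as given below, so a shared processing step stays open. Low signal limits dim genes: near the floor of 16 the size of a change depends on the floor.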

Other observations

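The families and genes named here outside the rule were chosen after their values were seen. So were the test on the scaling of the arrays, the share of falls by chitooctaose level and the filtered counts for falls. The other tests were set before their results. Tetraspanins, membrane proteins found in plant extracellular vesicles, had 15 measured genes, of which 3 rose. TET9 rose from 28.9 ± 4.80 to 316 ± 23.3 (SD, n = 3), a log2 change of 3.46 (adjusted p = 0.000122), or 2.30 with a floor of 64, and TET8 rose from 1483 ± 167 to 4765 ± 425. TET7 had a log2 change of 0.36, and its call was lost without each array but chitooctaose replicate 2 (adjusted p up to 0.129, without water replicate 1) and after quantile normalization (0.0615). Genes of endosomal sorting (ESCRT components) had 12 measured members, of which 4 rose: VPS2.1 from 564 ± 86.6 to 1211 ± 94.0, VPS60.1 from 311 ± 6.53 to 608 ± 61.7, and ELC and VPS46.2 with log2 changes of 0.38 and 0.31. The call of ELC was lost without each array but chitooctaose replicate 3 (adjusted p up to 0.117, without chitooctaose replicate 1), that of VPS46.2 without each but water replicate 1 (up to 0.122, without chitooctaose replicate 1), and both after median centring (0.0688 and 0.0547). The family passed camera among 25 families (adjusted p = 0.00293), but not with an estimated correlation (adjusted p = 0.842), and it had been picked for its called members. No other family passed camera.

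Of 14 measured bZIP transcription factor genes 3 rose, none fell and 11 did not pass, and adjusted over the list alone 3 rose and 1 fell (BZIP61, log2 change -0.44). The call of BZIP53 was lost without water replicate 1 (adjusted p = 0.0623) or 2 (0.0702) and chitooctaose replicate 2 (0.0779) or 3 (0.0685), and that of BZIP28 without water replicate 1 (0.116), 2 (0.0912) or 3 (0.0910) and chitooctaose replicate 1 (0.0770) or 3 (0.109). BZIP60, a factor gene of the unfolded protein response in the endoplasmic reticulum, rose from 898 to 2244, a log2 change of 1.32 (limma, adjusted p = 7.30e-05). GRX480, a glutaredoxin gene, rose from a water level near the floor, with 1 water array at it, and its log2 change was 2.82, or 1.18 with a floor of 64. DLAH, a lipase gene, rose 9.90-fold and ACA.l 5.94-fold. Among genes that fell was XERICO, a RING protein gene of abscisic acid responses, 2.32-fold, from 346 to 150 (adjusted p = 0.00807).

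Past the adjusted threshold more probe sets rose than fell, 964 against 183. At an unadjusted p under 0.05 (limma) the counts were closer, 1751 higher and 1443 lower. Both counts include the called probe sets, so among the smaller changes, past the unadjusted threshold alone, more fell than rose. The large excess of rises thus holds only for the changes past the adjusted threshold. The scaling of the arrays by the authors was tested as a source of this excess. After quantile normalization rises were still 78.2% of 1216 calls, which argues against it. Dim transcripts that can rise but not fall measurably were also argued against, as rises were 78.9% of the 659 calls in the brighter part of the probe sets, above the median water level. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many as 1147 changed probe sets, and the highest other gave 0. Every other split mixes the treatments in both groups, which widens their spread for genes that differ by treatment. Its count is therefore not that of arrays without a treatment effect. With so few splits a share under 0.05 cannot be reached either. Other processing before deposit stays open.

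Noise of dim probe sets was weighed for the 183 falls by their share among the dimmest 40% of probe sets. It was 17.5% by water level and 30.6% by chitooctaose level. A fall itself goes with a high level in water and a low one in chitooctaose, so neither share decides. Without the dimmest 40% of probe sets 210 fell, and without those touching the floor 241, with fewer probe sets tested in each. With a floor of 64, 158 fell. Falls were thus not confined to dim probe sets. With fewer probe sets tested the adjustment can be milder, so newly called falls can stand in for lost ones. These counts therefore do not decide whether noise of dim probe sets added to the 183 falls. Such noise stays open, for the falls as a set and for single dim ones. The numbers of falls and of rises were both lower with any array left out, as given above, which does not bear on dim probe sets alone.

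Calcium-binding and touch-induced genes respond to handling as well as to elicitors. Uneven handling of single tubes was weighed by the gap between the groups in the list's mean log2 level, 1.97. This gap was 19.8 times the larger range within a group, 0.10, so the rise was not that of single arrays. The list had already passed its tests on these same arrays, which takes a gap well above the spread. The ratio is therefore no separate evidence against uneven handling. A handling difference common to all treated tubes cannot be told apart from the treatment, because it would fall on the same arrays. Only 2 genes known first from touch, heat or low oxygen had a named probe set, too few for the planned check. They were AT4G10270 and AT4G17260, with a median log2 change of -0.33.

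The Bacillus subtilis control probe sets had a geometric mean intensity of 65.3 in water replicate 2 and 61.3 in chitooctaose replicate 2, and between 98.8 and 122 on the other arrays. The hybridisation controls stood at 1033 ± 26.6 in water and 939 ± 31.9 in chitooctaose (SD, n = 3). Their highest chitooctaose array, at 975, lay below their lowest water array, at 1014, and the cause was not tested. Replicate 2 was the lowest and replicate 3 the highest in both treatments, as for the Bacillus controls. Whether arrays of the same number shared a processing step stays open. The probe set of 25S ribosomal RNA read 1788 in water replicate 3 and between 606 and 930 on the others. Of the 64 control probe sets, limma called 0, and at an unadjusted p under 0.05 there were 0 higher and 2 lower.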
